A study of Mus musculus with 12 samples.

How the data were processed

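RNA of FACS-sorted Flk2-negative Lin-Sca-1+Kit+ mouse bone marrow cells was extracted with the RNeasy micro kit, enriched for polyA RNA and sequenced on the BGISEQ-500 (paired-end, 100 bp) per the labels' protocols. There were 12 libraries, 3 for each of 4 genotypes (Wild-type, Mdmx-Tg, Pu.1-URE-/- and Mdmx-Tg/Pu.1-URE-/-), and the labels gave each a mouse number of its own. FastQC, Salmon and DESeq2, with the builds mm10 and GRCm38, are named in the submitters' processing notes without versions or settings. Per the file headers, each deposited file holds Salmon's estimated counts per transcript (expected counts, not normalized), TPM as computed by the authors, and transcript lengths and effective lengths. The deposited estimated counts were not whole in 35.3% of values.

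Of 116248 transcripts, 115995 (99.8%) were matched with their version to the GENCODE M21 annotation of GRCm38, and the 253 others, with 0.0379% to 0.0841% of the reads of a library, were left out. Estimated counts were summed per gene and rounded. This gave 20698 genes with at least 1 read and 47271286 to 55067735 reads per library. Coordinates are those of the annotation. Xist was not in the transcript set, so sex was read from Y-linked genes alone. TPM values were used for the transcripts of Mdm4 and Spi1 only. The symbols Aldoa and Atp5o each have 2 gene identifiers, so glycolysis counts 24 measured genes for 23 listed.

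Gene tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM factors and fitted with a quasi-likelihood model with 1 mean per genotype over the 12 libraries. The 6 contrasts were Mdmx-Tg against Wild-type, Pu.1-URE-/- against Wild-type, the double mutant against each of the other 3 genotypes, and the interaction of transgene and element. Adjusted p-values are Benjamini-Hochberg over the 15012 genes tested, with a threshold of 0.05, or over a list alone where stated. CPM are TMM-scaled counts per 1e6 reads, given as mean ± SD of 3 libraries, and fold changes come from the model. Where a group had no read, folds are bounds against a floor of 3 reads over the group.

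Gene groups came from 31 lists (885 unique genes) written from general knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. The 29 lists tested were p53 target genes, Wnt/beta-catenin target genes, Wnt signalling components, haematopoietic stem cell genes, PU.1-dependent genes, granulocyte-monocyte progenitor genes, neutrophil markers, monocyte and macrophage markers, lymphoid priming genes, mature B cell and plasma cell markers, T cell and NK cell markers, erythroid genes, megakaryocyte genes, mast cell and basophil genes, dendritic cell and eosinophil markers, endothelial and stromal markers, S phase genes, G2/M phase genes, MYC and ribosome biogenesis genes, oxidative phosphorylation genes, cytosolic ribosomal protein genes, interferon response genes, NF-kappaB and inflammatory genes, immediate early and cell-handling stress genes, mitochondrially encoded genes, leukaemia-associated self-renewal genes, apoptosis regulators, glycolysis genes and cholesterol synthesis genes. Lists share members. They were tested on log2 CPM (prior count 2) with camera at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry (limma 3.58.1), each adjusted over the 29 lists. The remaining 2 lists, targeted genes and Y-linked genes, served to check labels and sex.

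Named genes were taken from a fixed rule: Mdm4 and Spi1; among called protein-coding genes with a mean log2 CPM of at least 2 and non-overlapping groups, excluding predicted and Y-linked genes, the 8 largest rises and 8 largest falls; for each list past the threshold or with at least 3 called members, up to 4 members with the smallest p; and for the p53 and Wnt target lists up to 4 members regardless. The text names a subset of these, picked after the values were seen. Some genes picked by the rule are not reported here. Genes outside the rule, behind counts of 4 or fewer, were named because they made up the count (1700047I17Rik2, Asb17, Mst1r, Pklr, Spon2, Gm15920, Gm15772 and Gm6594).

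Alternatives were relative log expression factors, DESeq2 1.42.0, limma-voom, no low-count filter, CPM over 1 in 3 libraries, a transcript length offset, only the groups compared, a replicate block, a block by the series of the mouse number (351 to 358, 371 to 373, and 380 to 384 with 396, the last pooled because it would have stood alone), Y-linked expression as a covariate, protein-coding genes only, and each library left out in turn. After seeing the data 5 were added: immunoglobulin genes left out, Jchain or the number of detected genes as a covariate, robust estimation, and 3 doubted libraries left out (Wild-type 1, Mdmx-Tg 2 and Mdmx-Tg/Pu.1-URE-/- 3). Log2 changes were also correlated between backgrounds, against 400 relabellings. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

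The gene test was tested on simulated data with the depth and spread of these libraries (3 runs of 14887 genes, 200 changed by known folds). Over the 3 runs 15 lists of 30 other genes were also raised by 1 log2 unit in the same libraries. It recovered 5.33% of genes changed 2-fold, 37.2% of those changed 4-fold, 51.0% at 8-fold and 68.5% at 16-fold, and called 9 of 43651 unchanged genes. Camera and fry each recovered 15 of 15 lists shifted by 1 log2 unit and called 0 and 1 of 75 unshifted lists. The simulated genes were not correlated with each other, so these list error rates do not carry over to real lists.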

Results

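RNA was profiled in Flk2-negative cells of the Lin-Sca-1+Kit+ bone marrow compartment, which holds the blood stem cells and early progenitors of the mouse, after flow-cytometric sorting. The 12 polyA-selected libraries fall into 4 genotypes with 3 libraries each, and the labels give every library its own mouse number. Wild-type animals were compared with Mdmx-Tg animals, which carry a transgene for MDMX (the product of Mdm4, an inhibitor of p53). The other genotypes were Pu.1-URE-/-, which lack the upstream regulatory element of Spi1 (the gene of the myeloid transcription factor PU.1), and the double mutant Mdmx-Tg/Pu.1-URE-/-. The design asks what extra MDMX does in stem and progenitor cells with and without the Spi1 element. Each library held 47271286 to 55067735 estimated reads, and 12824 to 14117 genes reached 10 reads. The p-values of the gene tests measure the spread between libraries of a genotype, estimated over all 12. Those of camera set the genes of a list against all other genes. At its preset correlation of 0.01 camera treats the genes of a list as nearly independent. The correlation estimated from the data reached 0.702, for cytosolic ribosomal protein genes.

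Loss of the upstream element was the main axis of the data. The first principal component held 29.1% of the variance and separated the 6 Pu.1-URE-/- and double-mutant libraries (68.1 to 119) from the 6 others (-116 to -65.3). The next 2 components held 12.03% and 9.06%. Libraries of 1 genotype correlated at 0.848 to 0.912 (log2 CPM), and the biological coefficient of variation was 0.796, a wide spread for 3 libraries per group. Some differences between libraries followed genotype only in part. Immunoglobulin genes took 31.2%, 10.3% and 0.427% of the reads in Wild-type 1, 2 and 3, against 3.79% to 10.6% in Mdmx-Tg, 0.573% to 3.07% in Pu.1-URE-/- and 0.131% to 4.13% in the double mutant. Their mean share was 14.0% and 7.10% in Wild-type and Mdmx-Tg, and 1.58% and 2.20% in Pu.1-URE-/- and the double mutant. Y-linked genes stood at 222 CPM in Wild-type 2, 205 in Mdmx-Tg/Pu.1-URE-/- 1 and 211 in Mdmx-Tg/Pu.1-URE-/- 3, and at 2.16 to 5.26 CPM in the other libraries. The libraries with high Y-linked reads were read as male. None of them was Mdmx-Tg or Pu.1-URE-/-, so sex was not balanced over the genotypes.

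Mdm4 (chromosome 1, 132959484 to 133030561, GRCm38) was highest in the transgenic libraries. It stood at 77.9, 70.9 and 35.8 CPM in Wild-type 1 to 3 and at 535, 414 and 163 CPM in Mdmx-Tg 1 to 3. Pu.1-URE-/- 1 to 3 had 93.9, 56.2 and 90.3 CPM, and the double mutant had 353, 163 and 210 CPM. All 6 transgenic libraries lay above all 6 others. Most of the excess was assigned to the 11-exon transcript Mdm4-201 (132991354 to 133025356), with 4477 to 22274 estimated reads in the transgenic libraries and 0 to 145 in the others. Smaller parts went to a retained-intron transcript (392 to 1937 against 0 to 104 reads) and to the non-coding Mdm4-212 (280 to 1243 against 0 to 97.7 reads). The longer Mdm4-210 (132986220 to 133025416) had 1799 to 4087 reads in every library. These transcripts were singled out after their values were seen.

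Spi1 (chromosome 2, 91082390 to 91115756) was low and variable. It stood at 37.98, 5.34 and 8.08 CPM in Wild-type, 21.6, 13.5 and 3.69 CPM in Mdmx-Tg, and 8.73, 8.73 and 23.9 CPM in Pu.1-URE-/-. In the double mutant it stood at 3.48, 1.84 and 0.0198 CPM. Total Spi1 therefore did not separate Pu.1-URE-/- from Wild-type. The 2-exon non-coding transcript Spi1-202 (91082408 to 91090310) ends upstream of the main coding transcript. It had 53 to 321 reads in the 6 libraries with the element and 0 in the 6 without it. This observation was made after the values were seen. A 4-exon coding transcript (91082390 to 91114366) has nearly the same first exon. It had 9.68, 49.3 and 15.4 reads in Pu.1-URE-/- 1, Pu.1-URE-/- 3 and Mdmx-Tg/Pu.1-URE-/- 1. It had 0 in the others without the element and 0 to 98.6 in those with it. Its later exons lie within those of the main coding transcript, so its estimated reads need not include the upstream first exon. These reads therefore leave open whether RNA from that exon was absent without the element, and Spi1-202 alone does not show it.

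**Figure D1:**
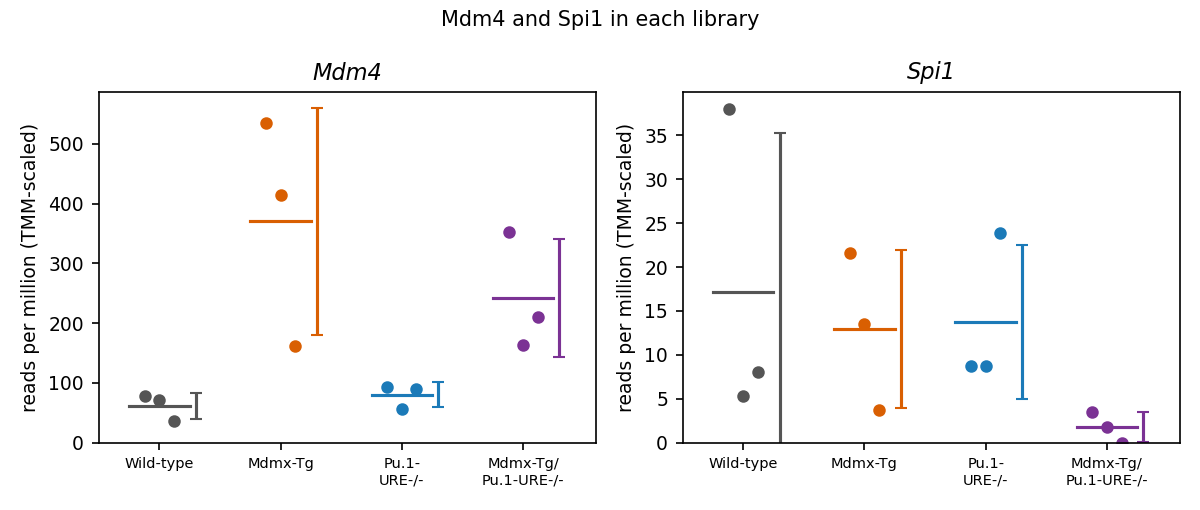
CPM (TMM-scaled) of Mdm4 and Spi1 in the 12 libraries by genotype; points are libraries, horizontal lines are means and vertical bars are 1 SD. Mdm4 lies at 163 to 535 CPM in the 6 transgenic libraries and at 35.8 to 93.9 CPM in the others, and Spi1 overlaps between Wild-type, Mdmx-Tg and Pu.1-URE-/-.

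Granulocyte genes rose in the libraries without the Spi1 element. The azurophil protease gene Elane (chromosome 10, 79886247 to 79888215) rose 74.7-fold, from 224 ± 66.5 CPM in Wild-type to 16724 ± 6490 in Pu.1-URE-/- (SD, n = 3 each; edgeR adjusted p = 0.000375). Of the 21 granulocyte-monocyte progenitor genes, 16 rose and 0 fell over all genes tested, and 19 rose and 1 fell adjusted over the list alone. Haptoglobin (Hp) rose 146-fold, cathepsin G (Ctsg) 27.9-fold and the vesicle adaptor Ap3s1 19.0-fold. The transcription factors Cebpa and Gfi1, which direct granulocyte differentiation, rose 22.4-fold and 21.2-fold, from 1.54 ± 0.547 to 34.4 ± 9.27 CPM and from 3.21 ± 0.680 to 68.0 ± 12.2 CPM. The list's median log2 change was 4.25 (camera adjusted p = 3.92e-19, or 0.113 with an estimated correlation). Fry gave this list an adjusted p of 6.79e-05.

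Neutrophil granule genes went from nearly absent to abundant. Of 13 neutrophil markers kept by the low-count filter, 12 rose, also adjusted over the list alone. Their median log2 change was 10.38, or 10.21 with the 2 genes that lack a read in Wild-type at their bound. The list's camera adjusted p was 7.35e-20, or 0.0880 with an estimated correlation, and its fry adjusted p was 6.29e-06. Without the filter 11 of all 19 listed markers were called higher and 0 lower (median 8.63, quartiles 2.74 to 12.07). The cathelicidin gene Camp stood at 0.699 ± 0.481 CPM in Wild-type and 17604 ± 11312 in Pu.1-URE-/-, and Ngp at 1.93 ± 0.807 and 32983 ± 18141. S100a8, a calcium-binding protein of myeloid cells, rose 1036-fold to 7604 ± 4177 CPM, and the secreted Lrg1 rose from 0.583 ± 0.576 to 1113 ± 616 CPM. Retnlg had no read in Wild-type and was at least 3108-fold higher in Pu.1-URE-/- against a floor of 3 reads over the group. Cd177 had 1 read in all of Wild-type and 962 ± 626 CPM in Pu.1-URE-/-, and the chitinase Chit1 had 2 reads and 620 ± 347 CPM. The 19 listed neutrophil markers together took 2.72% to 8.58% of the reads of Pu.1-URE-/- libraries and at most 0.00618% of those of Wild-type.

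Tbxas1, which encodes thromboxane synthase, fell 17.7-fold from 100 ± 1.69 to 5.66 ± 3.76 CPM. Other large falls were those of single genes: Serpinf1 fell 13.4-fold, the kinase gene Btk 12.6-fold, the growth factor gene Gdf3 20.97-fold, Lst1 13.7-fold and the ribonuclease gene Rnase6 26.2-fold. Nckap1l, a regulator of actin assembly in blood cells, fell 41.4-fold and the cytokine subunit gene Ebi3 26.9-fold. The 48 PU.1-dependent genes were split, with 16 that rose and 2 that fell (20 and 6 adjusted over the list alone). The list had a median log2 change of 0.53 and a camera adjusted p of 0.00333, or 0.580 with an estimated correlation. Its fry adjusted p was 0.0405. Those that rose included the oxidase subunit Ncf4 (23.1-fold) and the Fc receptor chain Fcer1g (11.4-fold). Cebpa and Gfi1, which rose, are on this list and on the granulocyte-monocyte progenitor list.

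**Figure D2:**
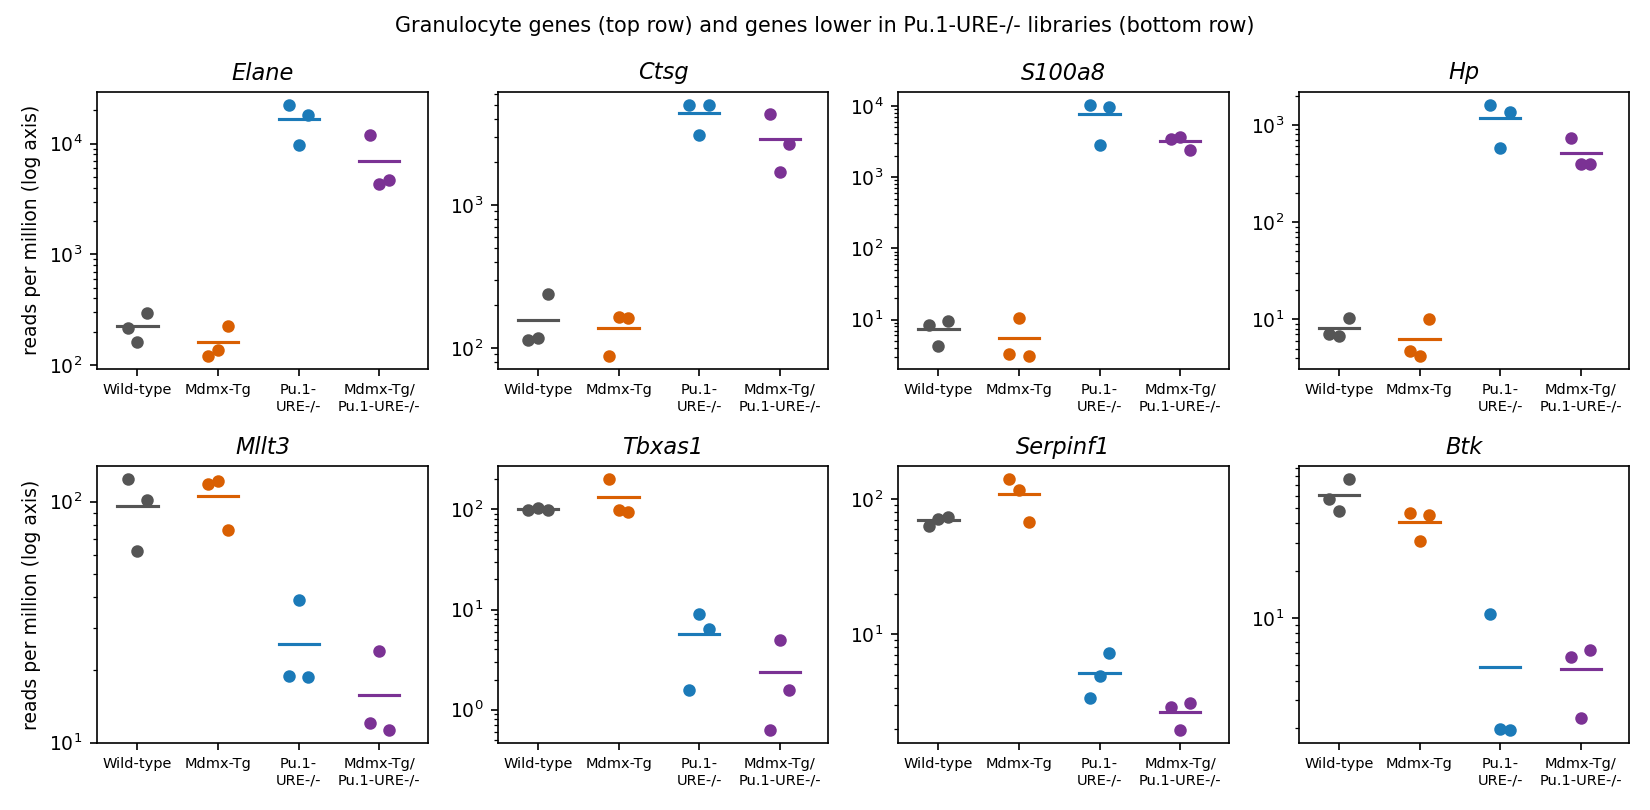
CPM (TMM-scaled, log axis) of 4 granulocyte genes that rose and 4 genes that fell in Pu.1-URE-/- against Wild-type, per library and genotype; horizontal lines are means. In each panel the 6 libraries without the Spi1 element lie on 1 side of the 6 with it; Elane means are 224 CPM in Wild-type and 16724 CPM in Pu.1-URE-/-.

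Stem cell genes leaned down in the same comparison. Of 42 haematopoietic stem cell genes 2 fell, also adjusted over the list alone, and 34 had a log2 change below 0 (median -0.84). The list's camera adjusted p was 4.09e-06, or 0.478 with an estimated correlation, and its fry adjusted p was 0.0405. Mllt3, a regulator of stem cell maintenance, fell 3.76-fold. Slamf1, which encodes the stem cell surface marker CD150, stood at 28.0 ± 8.39 and 4.05 ± 5.02 CPM without passing (log2 change -2.79, edgeR adjusted p = 0.0825). Erythroid genes had a median log2 change of -1.30 with 0 of 23 members called (camera adjusted p = 0.00303; adjusted p = 0.580 with an estimated correlation).

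Of 30 G2/M genes 3 rose, and 12 adjusted over the list alone (median 0.77, camera adjusted p = 1.59e-07; adjusted p = 0.580 with an estimated correlation). The kinesin gene Kif11 rose 2.57-fold and the kinase gene Cdk1 2.02-fold. The 30 S phase genes held 1 that rose (median 0.13, camera adjusted p = 0.141). The 32 MYC and ribosome biogenesis genes held 0 called over all genes and 19 that fell adjusted over the list alone (median -0.68, camera adjusted p = 1.59e-07; adjusted p = 0.547 with an estimated correlation). The nucleolin gene Ncl stood at a log2 change of -0.78. Of 63 cytosolic ribosomal protein genes 1 fell (Rps14, 2.12-fold), and 15 fell adjusted over the list alone (median -0.61, camera adjusted p = 6.12e-13; adjusted p = 0.580 with an estimated correlation). Glycolysis genes held 4 that rose and 1 that fell of 24 (9 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.0353; adjusted p = 0.580 with an estimated correlation). Gpi1 rose 5.34-fold, Pkm 3.41-fold and Eno1 4.11-fold.

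Of 38 interferon response genes 2 fell, the antiviral Oas1a 3.58-fold and the GTPase gene Gbp7 2.26-fold, and 4 fell adjusted over the list alone (median -0.55, camera adjusted p = 0.00839; adjusted p = 0.580 with an estimated correlation). Of 13 mature B cell and plasma cell markers 1 fell, the MHC class II gene H2-Eb1 (6.42-fold), and 5 fell adjusted over the list alone (median -2.82, camera adjusted p = 0.00527; adjusted p = 0.580 with an estimated correlation). Immunoglobulin genes took 31.2% of the reads of Wild-type 1, and without that library neither list passed (camera adjusted p = 0.140 for each). Mast cell and basophil genes had a median of -1.39 (camera adjusted p = 0.0200, 0.0754 without Wild-type 3; adjusted p = 0.547 with an estimated correlation), while the basophil protease Mcpt8 rose 9.18-fold. On the leukaemia-associated self-renewal list 1 of 46 rose (Clec12a, 13.3-fold) and 2 fell (Mef2c, 4.29-fold, and Bex3, 1.98-fold), with 4 and 3 adjusted over the list alone (median -0.07, mean 0.17, camera adjusted p = 0.759, direction down). Among 39 p53 target genes, 3 rose and 0 fell by either adjustment: the DNA repair gene Xpc 14.3-fold, the apoptosome gene Apaf1 2.88-fold and the membrane protein gene Perp 10.3-fold (list median 0.15, camera adjusted p = 0.350). Of 25 Wnt/beta-catenin target genes 1 rose, Id2 (4.56-fold), and 2 rose adjusted over the list alone (median -0.18, camera adjusted p = 0.833).

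The remaining lists did not pass camera in this comparison. They held 10 called genes over all genes tested, 8 higher and 2 lower, and 24 adjusted over the lists alone, 13 higher and 11 lower. Wnt signalling components had a median log2 change of -0.08 (adjusted p = 0.407), monocyte and macrophage markers -1.62 (0.133), lymphoid priming genes -0.41 (0.549, direction up), and T cell and NK cell markers -0.83 (0.130). Megakaryocyte genes stood at -0.47 (0.141), dendritic cell and eosinophil markers at 0.28 (0.950), and endothelial and stromal markers at 0.80 (0.407). Oxidative phosphorylation genes stood at -0.04 (0.663), NF-kappaB and inflammatory genes at 0.41 (0.270), immediate early and cell-handling stress genes at 0.45 (0.407), and mitochondrially encoded genes at 0.01 (0.927). Apoptosis regulators stood at 0.05 with a mean of -0.23 (0.822, direction up) and cholesterol synthesis genes at -0.16 (0.366).

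By edgeR's quasi-likelihood test, 707 of 15012 genes differed between Pu.1-URE-/- and Wild-type at a Benjamini-Hochberg adjusted p below 0.05, 577 higher and 130 lower. At unadjusted p 2968 genes passed, and 4453 genes had non-overlapping groups, where chance gives 10%. DESeq2 called 1881 genes (1176 higher). The count was 299 without Wild-type 2, 394 without Wild-type 3, 317 without Pu.1-URE-/- 1 and 303 without Pu.1-URE-/- 3. It was 422 with Jchain as a covariate and 257 with the series of the mouse number as a block. Of these 2 genotypes only Wild-type 1 and Pu.1-URE-/- 1 share a series. The block is therefore largely confounded with genotype here, and the lower count does not show an effect of the series. Camp, Ngp, S100a8, Retnlg, Lrg1, Elane, Hp, Ctsg, Ap3s1, Cebpa, Gfi1, Ncf4, Fcer1g, Serpinf1, Gdf3, Btk, Gpi1, Pkm, Oas1a, Xpc, Clec12a, Cd177, Chit1 and Mcpt8 stayed called whichever library was left out. The calls of Rnase6, Lst1 and Tbxas1 ended without 1 library (adjusted p = 0.0654 and 0.0547 without Pu.1-URE-/- 1, and 0.0628 without Pu.1-URE-/- 3). Nckap1l, Ebi3, Mllt3, Kif11, Cdk1, Rps14, Eno1, Gbp7, H2-Eb1, Mef2c, Bex3, Apaf1, Perp and Id2 lost their call without any of 3 to 10 libraries, at adjusted p up to 0.186 (Cdk1 without Pu.1-URE-/- 1). The glycolysis list lost its camera call without Wild-type 1 (adjusted p = 0.113) and 2 other libraries.

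The Mdmx transgene alone gave no single gene past the threshold, Mdm4 included. Mdm4 was 6.02-fold higher in Mdmx-Tg than in Wild-type (370.6 ± 189.9 against 61.5 ± 22.5 CPM; log2 change 2.59 ± 0.48, SE), with edgeR adjusted p = 0.259 and 1.51e-06 by DESeq2. Of the 6 lists that passed camera, the 13 mitochondrially encoded genes had a median log2 change of 0.63 (camera adjusted p = 5.07e-06; adjusted p = 0.212 with an estimated correlation; fry adjusted p = 0.00667). Their reads made up 3.03 ± 0.445% of the Mdmx-Tg libraries and 1.82 ± 0.503% of Wild-type, while Mdmx-Tg libraries also had fewer genes with 10 reads (13052 ± 255 against 13694 ± 375). None of the 13 was called over all genes, and 9 were higher adjusted over the list alone, among them mt-Nd4 (598 ± 97.3 and 975 ± 99.4 CPM), mt-Nd6 (76.7 ± 11.5 and 136 ± 25.7) and mt-Nd2 (196 ± 40.0 and 314 ± 52.1).

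Stem cell and self-renewal genes leaned up with the transgene, and cell cycle and erythroid genes leaned down. The 42 haematopoietic stem cell genes had a median log2 change of 0.43 (camera adjusted p = 0.00534; adjusted p = 0.715 with an estimated correlation). Mecom, a transcription factor of long-term stem cells, stood at 28.2 ± 7.50 and 78.2 ± 33.0 CPM (log2 change 1.47 ± 0.40, edgeR adjusted p = 0.367). The 46 leukaemia-associated self-renewal genes had a median of 0.60, or 0.55 with 1 gene that lacks reads in a group at its bound. Their camera adjusted p was 0.00219, or 0.715 with an estimated correlation. Among them Hoxa7 stood at 11.1 ± 1.90 and 21.5 ± 4.88 CPM and Erg at 10.7 ± 1.57 and 22.9 ± 13.7 CPM. Mecom and Erg are on both of these lists, so the lists are not separate evidence. S phase genes (median -0.28, camera adjusted p = 0.0182; adjusted p = 0.715 with an estimated correlation) included the ribonucleotide reductase gene Rrm1 at 428 ± 94.4 and 276 ± 38.04 CPM and the replicative helicase gene Mcm7 at 243 ± 68.1 and 145 ± 66.2 CPM. G2/M genes (median -0.30, camera adjusted p = 0.00704; adjusted p = 0.715 with an estimated correlation) included the kinase gene Aurkb at 126 ± 21.7 and 71.8 ± 29.9 CPM. Erythroid genes had a median of -1.06 (camera adjusted p = 0.00219; adjusted p = 0.715 with an estimated correlation), with the transferrin receptor gene Tfrc at 132 ± 9.004 and 74.5 ± 46.4 CPM. No member of these 5 lists was called over all genes or adjusted over the list alone.

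The targets of p53 and of Wnt did not pass in Mdmx-Tg. The 39 p53 target genes had a median log2 change of -0.14 (camera adjusted p = 0.514; 0 called by either adjustment), with the exonuclease gene Aen at 109 ± 15.5 and 79.1 ± 9.40 CPM and Perp at 1.504 ± 0.370 and 5.16 ± 0.844 CPM. The 25 Wnt/beta-catenin target genes had a median of 0.43 (camera adjusted p = 0.358; 0 called by either adjustment), with the cyclin gene Ccnd1 at 15.5 ± 1.08 and 40.5 ± 23.2 CPM and Sox4 at 68.0 ± 5.59 and 126 ± 40.6 CPM. Lists whose median and mean differed in sign from camera's direction, all far from the threshold, were the lymphoid priming genes, mature B cell and plasma cell markers, cytosolic ribosomal protein genes and apoptosis regulators, while for T cell and NK cell markers the median (0.04) differed from the mean (-0.33).

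edgeR's quasi-likelihood test called 0 of 15012 genes between Mdmx-Tg and Wild-type, with 1576 at an unadjusted p below 0.05 and 2051 with non-overlapping groups, where chance gives 10%; limma-voom called 0 and DESeq2 329 (154 higher). Without Mdmx-Tg 3, edgeR called 109 genes, Mdm4 among them (adjusted p = 0.0319). Of the 6 lists past camera, 4 lost their call without 1 library: haematopoietic stem cell and erythroid genes without Mdmx-Tg 1 (adjusted p = 0.150 and 0.112), and S phase and G2/M genes without Wild-type 3 (0.384 and 0.338) and others. Other lists gained a call without 1 library, among them MYC and ribosome biogenesis and interferon response genes without Wild-type 1 (camera adjusted p = 0.014 each). With the series of the mouse number as a block, in which Wild-type 3 was pooled with the nearest series, only the mitochondrially encoded genes passed (camera adjusted p = 1.84e-05).

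In animals without the Spi1 element the transgene went with lower granulocyte and higher self-renewal genes as lists by camera at its preset correlation only, again with no single gene past the threshold. Mdm4 was 3.02-fold higher in the double mutant than in Pu.1-URE-/- (242 ± 98.8 against 80.1 ± 20.8 CPM; log2 change 1.59 ± 0.46, SE; edgeR adjusted p = 0.406), and Spi1 stood at 1.78 ± 1.73 against 13.8 ± 8.74 CPM (log2 change -2.95 ± 1.27; edgeR adjusted p = 0.453). The 21 granulocyte-monocyte progenitor genes had a median log2 change of -0.98 (camera adjusted p = 3.84e-05; adjusted p = 0.709 with an estimated correlation). The protease genes Prtn3 and Elane stood at 920 ± 577 against 2383 ± 846 CPM and at 6968 ± 4304 against 16724 ± 6490 CPM, and the lysozyme gene Lyz2 at 369 ± 92.1 against 771 ± 421 CPM. The 13 neutrophil markers had a median of -1.26 (camera adjusted p = 0.0163; adjusted p = 0.709 with an estimated correlation), with S100a8 at 3176 ± 683 against 7604 ± 4177 CPM. The share of reads on neutrophil markers was 2.45% to 3.03% in the double mutant, a range that includes Pu.1-URE-/- 2 (2.72%). The 46 leukaemia-associated self-renewal genes had a median of 0.34 (camera adjusted p = 0.00529; adjusted p = 0.709 with an estimated correlation). The progenitor surface gene Cd34 stood at 257 ± 94.8 against 97.4 ± 30.4 CPM, Sox4 at 133 ± 38.8 against 58.4 ± 37.4 CPM and Hoxa7 at 22.6 ± 4.30 against 10.96 ± 4.74 CPM.

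Erythroid, mitotic, mitochondrial and stress-response lists also passed camera at its preset correlation. Erythroid genes had a median of -0.84 (camera adjusted p = 0.000108; adjusted p = 0.709 with an estimated correlation), although Hemgn stood higher, at 132 ± 11.7 against 72.6 ± 20.2 CPM, and G2/M genes had a median of -0.45 (camera adjusted p = 0.000172; 0.709 with an estimated correlation), with Kif11 at 175 ± 8.28 against 278 ± 92.3 CPM and Cks2 at 212 ± 33.4 against 327 ± 48.0 CPM. Mitochondrially encoded genes had a median of 0.42 (camera adjusted p = 0.00825; 0.709 with an estimated correlation), with mt-Co2 at 968 ± 182 against 659 ± 2.59 CPM, and their share of reads was 2.62 ± 0.537% against 1.65 ± 0.184%. Immediate early and cell-handling stress genes had a median of -0.99 (camera adjusted p = 0.00395; 0.709 with an estimated correlation), with Fos at 72.9 ± 51.7 against 282 ± 170 CPM. Cytosolic ribosomal protein genes had a median of 0.15 (camera adjusted p = 0.0163; adjusted p = 0.826 with an estimated correlation), with Rpl3 at 640 ± 150 against 179 ± 42.8 CPM. No member of the 8 lists that passed was called over all genes or adjusted over the list alone. The haematopoietic stem cell genes did not pass (median 0.12, mean -0.37, camera adjusted p = 0.534, direction up), with 0 called over all genes and 3 that fell adjusted over the list alone.

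The 39 p53 target genes had a median of -0.12 in this comparison (camera adjusted p = 0.325; 0 called by either adjustment). The cell cycle inhibitor gene Cdkn1a, a classical p53 target, stood at 10.5 ± 5.62 against 34.5 ± 22.1 CPM, and the survival gene Bcl2l1 at 18.1 ± 9.47 against 43.4 ± 11.5 CPM, while Fbxw7 stood higher, at 29.2 ± 14.4 against 15.7 ± 3.00 CPM. The 25 Wnt/beta-catenin target genes had a median of 0.25 (camera adjusted p = 0.292; 0 called by either adjustment), with Ccnd1 at 31.4 ± 7.08 against 13.8 ± 6.24 CPM, the drug transporter gene Abcb1b at 9.65 ± 2.46 against 2.56 ± 1.23 CPM and the Wnt feedback gene Znrf3 at 109 ± 39.3 against 46.9 ± 21.1 CPM. Median, mean and camera's direction also differed in sign for monocyte and macrophage markers, lymphoid priming genes, mature B cell and plasma cell markers, interferon response genes and apoptosis regulators, none past the threshold.

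edgeR called 0 of 15012 genes between the double mutant and Pu.1-URE-/-, with 1601 at an unadjusted p below 0.05 and 2829 with non-overlapping groups, where chance gives 10%; limma-voom called 0 and DESeq2 329 (137 higher), Mdm4 (adjusted p = 0.0283) and Cd34 (0.00726) among them. Without Mdmx-Tg/Pu.1-URE-/- 2 edgeR called 4 genes (Mst1r, Spon2, Asb17 and Pklr), without Pu.1-URE-/- 2 it called 1 (1700047I17Rik2), genes named here after their values were seen. Only the granulocyte-monocyte progenitor and erythroid lists passed camera whichever library was left out. The neutrophil list lost its call without any of 8 libraries (adjusted p up to 0.555, without Pu.1-URE-/- 1), the ribosomal list without any of 4 (up to 0.677, without Mdmx-Tg/Pu.1-URE-/- 2) and the self-renewal list without either of 2 (up to 0.126, without Pu.1-URE-/- 1). The G2/M and mitochondrial lists lost it without Pu.1-URE-/- 1 (0.0968 and 0.0509) and the stress list without Mdmx-Tg/Pu.1-URE-/- 2 (0.0627).

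**Figure D3:**
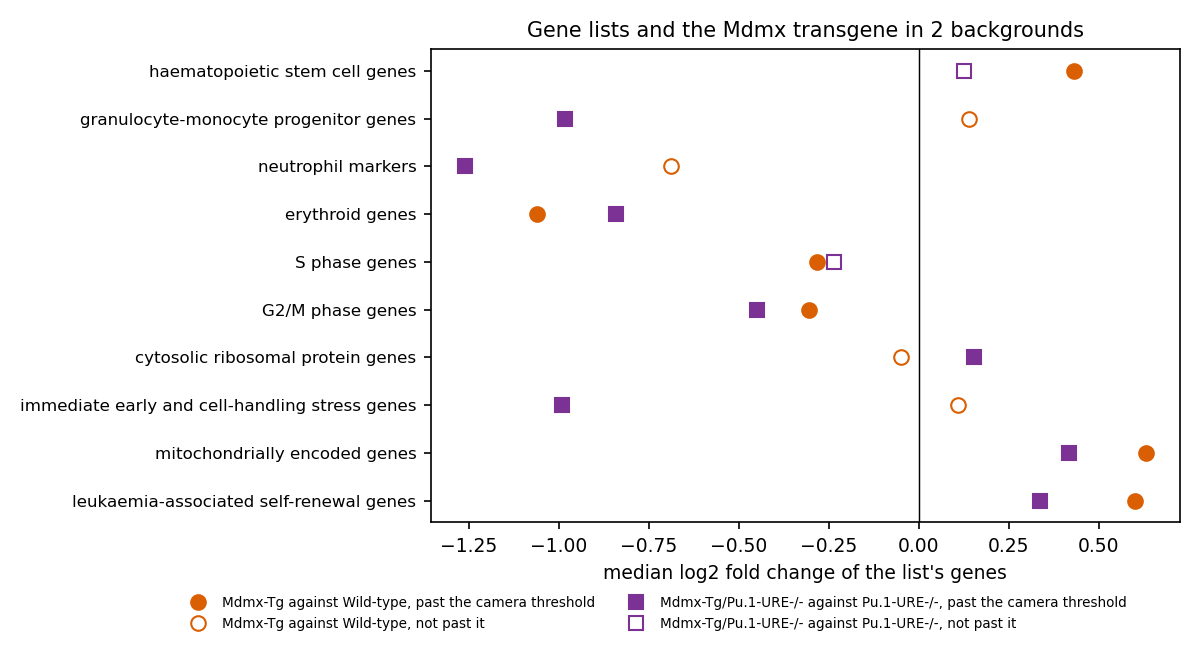
Median log2 fold change of the genes of 10 fixed lists with the Mdmx transgene, in animals with the Spi1 element (orange circles) and without it (purple squares); filled symbols passed camera at its preset correlation and open symbols did not. Mitochondrially encoded genes have medians of 0.63 and 0.42, and granulocyte-monocyte progenitor genes of 0.14 and -0.98.

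With the transgene in both groups, loss of the Spi1 element again went with higher granulocyte genes and lower stem cell genes. In the double mutant against Mdmx-Tg, 11 of 21 granulocyte-monocyte progenitor genes rose (17 rose and 1 fell adjusted over the list alone). Their median log2 change was 2.87 (camera adjusted p = 5.75e-14, or 0.165 with an estimated correlation, and fry adjusted p = 0.000735). Of 13 neutrophil markers 10 rose (12 adjusted over the list alone), with a median of 11.46, or 9.16 with 2 genes at their bound. For these markers camera gave an adjusted p of 3.25e-22, or 0.0633 with an estimated correlation, and fry gave 8.48e-06. Elane rose 43.1-fold, Hp 80.8-fold and S100a8 571-fold, and Camp went from 0.305 ± 0.235 to 8288 ± 663 CPM. The adhesion gene Vcam1 rose 115-fold, the myeloid receptor gene Trem3 157-fold and Clu, which encodes clusterin, 88.4-fold. Of 42 haematopoietic stem cell genes 6 fell, and 14 fell and 1 rose adjusted over the list alone (median -1.04). The list's camera adjusted p was 1.84e-10, or 0.165 with an estimated correlation, and its fry adjusted p was 0.00641. Mllt3 fell 6.69-fold and Mecom 4.98-fold, and the receptor gene Tek stood at 39.3 ± 23.9 CPM in Mdmx-Tg and had 2 reads in the 3 double-mutant libraries together. Serpinf1 fell 40.8-fold, Tbxas1 55.5-fold, Lst1 28.0-fold, Tspan8 25.01-fold, Pcp4l1 22.9-fold, Rnase6 26.0-fold and the inhibitory receptor gene Cd300a 54.4-fold.

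Of 38 interferon response genes 2 fell, Oas1a 7.25-fold and Gbp7 2.17-fold, and 5 adjusted over the list alone (median -0.59, camera adjusted p = 1.24e-05; adjusted p = 0.423 with an estimated correlation). Of 30 G2/M genes 1 rose by either adjustment, Cdk1 2.20-fold (median 0.62, camera adjusted p = 2.32e-06; adjusted p = 0.595 with an estimated correlation). Erythroid genes (median -1.26, camera adjusted p = 5.75e-05; 0.595 with an estimated correlation) and mature B cell and plasma cell markers (median -1.86, camera adjusted p = 0.00175; 0.595 with an estimated correlation) held 0 called over all genes, with 2 of the latter lower adjusted over the list alone. MYC and ribosome biogenesis genes (median -0.39, camera adjusted p = 0.000180) and cytosolic ribosomal protein genes (median -0.44, camera adjusted p = 1.25e-09) held 0 called by either adjustment. The latter 2 lists had an adjusted p = 0.595 with an estimated correlation. Of 48 PU.1-dependent genes 5 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.06), and the list did not pass (camera adjusted p = 0.419). S phase genes (median 0.27, camera adjusted p = 0.0418; adjusted p = 0.741 with an estimated correlation) and immediate early and cell-handling stress genes (median -0.54, camera adjusted p = 0.0303; adjusted p = 0.619 with an estimated correlation) lost their call without Mdmx-Tg 1 (adjusted p = 0.378 for each) and other libraries. Of 39 p53 target genes 1 rose by either adjustment, Xpc (9.21-fold; list median 0.09, camera adjusted p = 0.383), and of 25 Wnt/beta-catenin target genes 0 were called (median 0.23, mean -0.24, camera adjusted p = 0.961). On the self-renewal list Clec12a rose 13.3-fold, and Socs2 (19.3-fold) and Mecom fell; 3 rose and 4 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.550, direction down).

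In all, edgeR called 348 genes between the double mutant and Mdmx-Tg, 251 higher and 97 lower, with 2538 at an unadjusted p below 0.05 and 2878 with non-overlapping groups, where chance gives 10%; DESeq2 called 1289 (751 higher). The count was 136 without Mdmx-Tg/Pu.1-URE-/- 1, 164 without Mdmx-Tg 1, 181 without Mdmx-Tg/Pu.1-URE-/- 3, 202 without Mdmx-Tg 2 and 213 without Pu.1-URE-/- 3, and 92 with Y-linked expression as a covariate. The calls of Clu, Cd300a, Rnase6, Mecom, Tek, Gbp7, Cdk1 and Socs2 ended without any of 3 to 10 libraries, at adjusted p up to 0.178 (Cdk1 without Mdmx-Tg 1).

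Against Wild-type, the double mutant combined the granulocyte rise with a higher Mdm4. Mdm4 rose 3.93-fold (log2 change 1.98 ± 0.46, SE; edgeR adjusted p = 0.0439), a call that ended without any of 10 libraries (adjusted p = 0.189 without Mdmx-Tg/Pu.1-URE-/- 1), and Spi1 stood at a log2 change of -3.27 ± 1.29 (edgeR adjusted p = 0.209). Of 21 granulocyte-monocyte progenitor genes 13 rose (18 rose and 1 fell adjusted over the list alone; median 2.88, camera adjusted p = 1.09e-14; adjusted p = 0.220 with an estimated correlation) and of 13 neutrophil markers 10 rose (12 adjusted over the list alone; median 9.48, or 8.76 with 2 genes at their bound, camera adjusted p = 1.51e-19; adjusted p = 0.0921 with an estimated correlation). Elane rose 31.1-fold, Hp 63.4-fold and S100a8 433-fold, Retnlg was at least 1342-fold higher against the same floor of 3 reads, and the sphingomyelin synthase gene Sgms2 rose 119-fold. Of 42 haematopoietic stem cell genes 4 fell, and 6 adjusted over the list alone (median -0.53, camera adjusted p = 0.000109; adjusted p = 0.494 with an estimated correlation): Mllt3 fell 6.10-fold, Tek went from 28.6 ± 4.67 CPM to 2 reads in 3 libraries, and Hoxb5 and the cell cycle inhibitor gene Cdkn1c, without a read in the double mutant, were at least 179-fold and 123-fold lower against that floor. Erythroid genes had a median of -2.08 with 0 of 23 called (camera adjusted p = 1.34e-09; adjusted p = 0.494 with an estimated correlation; fry adjusted p = 0.0453).

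Single lymphoid priming and self-renewal genes were called, in both directions, while neither list passed camera. On the lymphoid priming list Notch1 rose 3.90-fold, Satb1 rose 4.71-fold and Bcl11a fell 2.25-fold (5 rose and 2 fell adjusted over the list alone; median -0.29, camera adjusted p = 0.848, direction up). On the self-renewal list Cd96 rose 7.29-fold, Clec12a rose 9.50-fold and Socs2 fell 18.7-fold (8 rose and 4 fell adjusted over the list alone; median 0.33, camera adjusted p = 0.106). Of 39 p53 target genes Xpc rose 8.76-fold and Apaf1 2.82-fold, and 4 rose and 1 fell adjusted over the list alone (median -0.14, mean 0.22, camera adjusted p = 0.891). Of 25 Wnt/beta-catenin target genes 0 were called by either adjustment (median 0.37, camera adjusted p = 0.470), with Id2 at 41.7 ± 12.5 against 10.3 ± 4.35 CPM and Cd44 at 197 ± 16.2 against 115 ± 7.23 CPM. Of 32 MYC and ribosome biogenesis genes 2 fell, Nop2 2.23-fold and Pes1 2.02-fold, and 8 adjusted over the list alone (median -0.62, camera adjusted p = 1.34e-07; adjusted p = 0.494 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.44 with 0 called by either adjustment (camera adjusted p = 1.95e-08; adjusted p = 0.681 with an estimated correlation). Interferon response genes had 1 that fell, Oas1a 3.98-fold (2 adjusted over the list alone; median -0.48, camera adjusted p = 0.00256; adjusted p = 0.494 with an estimated correlation), and mature B cell and plasma cell markers 1 that fell and 4 adjusted over the list alone (median -2.44, camera adjusted p = 0.00542; adjusted p = 0.681 with an estimated correlation). Without Wild-type 1, where 31.2% of the reads were immunoglobulin, the latter 2 lists did not pass (adjusted p = 0.0708 and 0.180). Mitochondrially encoded genes (median 0.42) and G2/M genes (median 0.30) passed camera at adjusted p = 0.0274 each (adjusted p = 0.494 and 0.765 with an estimated correlation), and lost it without Wild-type 3 (0.152) and Wild-type 1 (0.644) and others.

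edgeR called 502 genes between the double mutant and Wild-type, 131 of them lower, with 2772 at an unadjusted p below 0.05 and 3906 with non-overlapping groups, where chance gives 10%; DESeq2 called 1547 (857 higher). The count was 231, 162 and 179 without Wild-type 1, 2 and 3, 167 and 236 without Mdmx-Tg/Pu.1-URE-/- 1 and 3, and 314 without Pu.1-URE-/- 3. It was 178 with Y-linked expression as a covariate, which was high in 1 Wild-type and 2 double-mutant libraries, and 167 with Jchain as a covariate. The calls of Sgms2, Tek, Notch1, Satb1, Bcl11a, Cd96, Socs2, Nop2, Pes1 and Apaf1 ended without any of 2 to 8 libraries, at adjusted p up to 0.162 (Satb1 without Mdmx-Tg/Pu.1-URE-/- 1).

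Whether the transgene acted differently without the Spi1 element was tested as an interaction. edgeR called 0 of 15012 genes, with 871 at an unadjusted p below 0.05; limma-voom called 0 and DESeq2 194 (86 higher). As lists, granulocyte-monocyte progenitor genes had a median difference of -0.83 (camera adjusted p = 7.10e-05), PU.1-dependent genes -0.48 (0.00526), immediate early and cell-handling stress genes -0.93 (0.00526) and NF-kappaB and inflammatory genes -0.51 (0.0350), each with an adjusted p = 0.975 with an estimated correlation and 0 members called over all genes. Cebpa stood at 1.54 ± 0.547 CPM in Wild-type and 7.61 ± 1.38 in Mdmx-Tg, and at 34.4 ± 9.27 in Pu.1-URE-/- and 19.9 ± 9.04 in the double mutant (difference of log2 changes -3.10 ± 0.59, SE; edgeR adjusted p = 0.681, DESeq2 0.000132). Lyz2 stood at a difference of -1.75 ± 0.51 and Prtn3 at -1.56 ± 0.59. Adjusted over the list alone, 1 PU.1-dependent gene and 1 granulocyte-monocyte progenitor gene were lower. Cebpa and Lyz2 are on both of these lists, so the lists are not separate evidence. The granulocyte-monocyte progenitor list passed whichever library was left out, while the other 3 lists did not pass without Wild-type 3 (adjusted p = 0.114, 0.214 and 0.155 for the PU.1-dependent, stress and NF-kappaB lists) and others.

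Across 15012 genes, which are not independent replicates, the log2 change with loss of the Spi1 element correlated between animals without and with the transgene (Pearson r = 0.595, Spearman 0.475). In 400 relabellings of the libraries within the groups compared, the highest r of another labelling was 0.428, and the p of 0.01 is the smallest they can give. The log2 change with the transgene correlated weakly between animals with and without the element (r = 0.130, relabelling p = 0.04, highest other 0.151; Spearman 0.221, p = 0.01). It lay between 0.0617 without Wild-type 1 (p = 0.24) and 0.150 without Wild-type 3, and its p was also above the threshold without Mdmx-Tg 1 (r = 0.118, p = 0.06), Mdmx-Tg 2 (0.0740, p = 0.23), Pu.1-URE-/- 1 (0.1, p = 0.11) and Mdmx-Tg/Pu.1-URE-/- 3 (0.0943, p = 0.09). These 2 correlations used separate libraries for each of their sides.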

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

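The tests of cell content, complexity and transgene in this part were chosen after the results were seen, and those on regroupings of the libraries before.

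The effect of the Mdmx transgene differed between the backgrounds for 4 gene lists, by a test of the difference itself that passed only at the preset correlation. Camera gave an adjusted p of 7.10e-05 for granulocyte-monocyte progenitor genes, 0.00526 for PU.1-dependent genes, 0.00526 for immediate early and cell-handling stress genes and 0.0350 for NF-kappaB and inflammatory genes, and 0.975 for each with an estimated correlation. The granulocyte-monocyte progenitor and PU.1-dependent lists share members, Cebpa and Lyz2 among them. Over each list's alternatives the adjusted p reached 0.999 with fry, and the call ended for PU.1-dependent and NF-kappaB genes without Mdmx-Tg/Pu.1-URE-/- 2 (0.144 and 0.184) and for immediate early genes without Wild-type 3 (0.214). Of 100 regroupings of the 12 libraries, 81 gave at least the 4 lists of the real grouping and the highest other gave 15. These regroupings also spread the large effect of the Spi1 element over the regrouped genotypes. They therefore cannot decide whether chance accounts for the number of lists. For genes, edgeR called 0 in the real grouping (871 at an unadjusted p below 0.05, limma-voom 0, DESeq2 194), with 2 the highest other. Any regrouping reaches a count of 0, so that all 100 did decides nothing.

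Neutrophil markers rose in the libraries without the Spi1 element. Mature neutrophils, which the lineage gate removes, may contribute and stay open: in a fit without the low-count filter 16 late neutrophil genes had a median log2 change of 1.185 (quartiles -0.33 to 6.79), against 8.63 for all 19 neutrophil markers (5 on both lists), with Retnlg, Il1r2 and Clec4e called higher. This median decides nothing, since the log2 changes of Fpr1, Fpr2, Mmp8 and Mmp9 rest on almost no reads, and the upper quartile rests in part on Fpr1. As levels the late genes were split in Pu.1-URE-/-: Mmp8 and Mmp9 stood at 0 CPM, while Retnlg stood at 58.2 ± 29.5 and Il1r2 at 76.8 ± 45.5 CPM. Of the 16, Cxcr2, Mmp8, Mmp9 and Il1b had no higher mean in Pu.1-URE-/- than in Wild-type (Cxcr2 3.11 ± 1.44 against 7.79 ± 4.72 CPM), and as a test these 4 seemed to exclude mature neutrophils, which was withdrawn because they were picked with their values known. A larger share of granulocyte precursors inside the gate may explain the rise and stays open: it would lower stem cell genes, whose median log2 change was -0.8395 (34 of 42 below 0, SD 1.12 against a median SE of 0.499).

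Mitochondrially encoded genes passed camera between Mdmx-Tg and Wild-type at its preset correlation (adjusted p = 5.07e-06) but not at an estimated one (0.212), with 0 of 13 members called (median log2 change 0.63, median SE 0.218). Lower complexity of the Mdmx-Tg libraries could contribute: with the number of detected genes as a covariate the median was 0.4373 (median SE 0.2998). The bound for excluding it was tightened after this value was seen, which moved the outcome from excluded to open. An effect of the transgene also stays open, since fry gave an adjusted p of 0.1828 for the same list between the double mutant and Pu.1-URE-/-, where its median was 0.42.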

How the results depend on the processing

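The alternatives with Jchain, detected genes, immunoglobulin genes left out, robust estimation and 3 doubted libraries left out were chosen after seeing the data. For the counts of genes and lists and the 2 correlations, 242 alternative values stayed on their side or within 1.5 times, 64 moved and 5 became weaker. For named genes 4493 kept direction and side, 433 became weaker, 64 stronger and 11 reversed. The cause was not tested unless stated.

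DESeq2 called more genes in each comparison: 329 for Mdmx-Tg against Wild-type, 1881 for Pu.1-URE-/- against Wild-type, 329, 1289 and 1547 for the double mutant against Pu.1-URE-/-, Mdmx-Tg and Wild-type, and 194 for the interaction, where edgeR called 0, 707, 0, 348, 502 and 0. With only the groups compared, 1 gene was called for Mdmx-Tg against Wild-type (Gm15920) and 1 for the double mutant against Pu.1-URE-/- (Gm15772). With the animal number block, 257 were called for Pu.1-URE-/- against Wild-type and 156 for the double mutant against Mdmx-Tg. In the former comparison the number series is largely confounded with genotype. With Y-linked expression as covariate, 92 and 178 were called for the double mutant against Mdmx-Tg and Wild-type.

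With Jchain as covariate, 422 genes were called for Pu.1-URE-/- against Wild-type, and 104 and 167 for the double mutant against Mdmx-Tg and Wild-type. With genes detected as covariate the latter were 192 and 283, and with 3 doubted libraries left out, which leaves fewer samples, 111 and 147, with 1 (Gm6594) for the double mutant against Pu.1-URE-/-. Relative log expression factors, no filter, CPM over 1, the length offset, limma-voom, the replicate block, protein-coding genes only, immunoglobulin genes left out and robust estimation stayed within 1.5 times. The replicate block has no pairing behind it: residual correlations of libraries with the same replicate number were -0.153 to 0.0856.

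The number of lists past camera fell from 6, 12, 8, 11, 10 and 4 to 0 in all 6 comparisons with an estimated correlation. With fry it was 1 for Mdmx-Tg against Wild-type, 4 for Pu.1-URE-/- against Wild-type, 0, 3 and 5 for the double mutant against Pu.1-URE-/-, Mdmx-Tg and Wild-type, and 0 for the interaction. For Mdmx-Tg against Wild-type it was 1 with the animal number block, 11 with 3 doubted libraries left out and 10 with genes detected as covariate.

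Leaving out each library gave 0 to 109 genes for Mdmx-Tg against Wild-type (109 without Mdmx-Tg 3), 299 to 789 for Pu.1-URE-/- against Wild-type (299 without Wild-type 2), 0 to 4, 136 to 347 and 162 to 565 for the double mutant against Pu.1-URE-/-, Mdmx-Tg and Wild-type (4 without Mdmx-Tg/Pu.1-URE-/- 2, 136 without Mdmx-Tg/Pu.1-URE-/- 1, 162 without Wild-type 2), and 0 to 0 for the interaction. The lists numbered 2 to 13, 9 to 13, 3 to 10, 9 to 14, 8 to 11 and 2 to 7. The correlation of the transgene effect ranged from 0.0617 without Wild-type 1 to 0.150, with 5 weaker values, and that of the element effect from 0.520 to 0.583. Where a group was left with 2 libraries, its spread was taken from all groups.

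Spi1 log2 fold change, Mdmx-Tg versus Wild-type, was not called (-0.41) and reversed to 0.2296 with the length offset, 3.124 with genes detected as covariate and 0.9294 with 3 doubted libraries left out. Leaving out 1 library gave -1.004 (Mdmx-Tg 1) to 0.9513 (Wild-type 1), with 0.03312 without Mdmx-Tg 3.

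Spi1 log2 fold change, Pu.1-URE-/- versus Wild-type, was not called (-0.31) and reversed to 0.177 with limma-voom, 0.5158 with the replicate block, 0.517 with genes detected as covariate and 1.048 with 3 doubted libraries left out. Leaving out 1 library gave -1.012 (Pu.1-URE-/- 3) to 1.048 (Wild-type 1). Reads of Spi1 were few, down to 1 in Mdmx-Tg/Pu.1-URE-/- 3.

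Mdm4 log2 fold change, Pu.1-URE-/- versus Wild-type, was not called (0.38) and reversed to -0.1665 with the animal number block.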

Other observations

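The comparisons of splits in this part were planned. The tests of plasma cell RNA, immunoglobulin reads and loss of the element were chosen after the result was seen, and the transcripts of Mdm4 and Spi1 were looked at after their values were seen.

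The Mdm4 excess of the transgenic libraries lay mainly in transcript Mdm4-201, at 169 ± 110 TPM in Mdmx-Tg and 92.8 ± 62.1 TPM in the double mutant against 0.239 ± 0.415 in Wild-type and 1.09 ± 0.946 in Pu.1-URE-/-. The long Mdm4-210 stood at 6.62, 6.12, 9.66 and 9.99 TPM in Wild-type, Mdmx-Tg, Pu.1-URE-/- and the double mutant. The coding transcript Spi1-201 stood at 5.42, 4.55, 7.01 and 0.985 TPM, while Spi1-202 was read in the 6 libraries with the element and in 0 of the 6 without it. The coding transcript with nearly the same first exon as Spi1-202 (91082390 to 91114366) did not follow this pattern. It stood at 1.63, 2.68, 1.13 and 0.367 TPM in the same order of genotypes. These estimates may hold reads of exons shared with Spi1-201.

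Each comparison of 2 genotypes has 10 splits of its 6 libraries, too few for a share under 0.05. With edgeR the real split gave 0 genes for Mdmx-Tg against Wild-type (10 splits as large; highest other 1), 0 for the double mutant against Pu.1-URE-/- (10; 2), 348 against Mdmx-Tg (1; 5) and 502 against Wild-type (1; 3). Any split reaches a count of 0, so where the real count was 0 the number of splits as large decides nothing. Where the count was 0, 1576 and 1601 genes passed an unadjusted p of 0.05, and limma-voom called 0 and 0. With DESeq2 the real split gave 329 for Mdmx-Tg against Wild-type (1; 309) and 329 for the double mutant against Pu.1-URE-/- (1; 263), so its counts there had nearly as large counterparts.

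Lists past camera numbered 6 for Mdmx-Tg against Wild-type (5 splits as large; highest other 15), 12 for Pu.1-URE-/- against Wild-type (3; 12), and 8, 11 and 10 for the double mutant against Pu.1-URE-/- (3; 10), Mdmx-Tg (3; 13) and Wild-type (3; 10). The split of Wild-type 1, Mdmx-Tg 1 and Mdmx-Tg 2 from Wild-type 2, Wild-type 3 and Mdmx-Tg 3 keeps each series of mouse numbers on 1 side, with Wild-type 3 pooled with the nearest series, and gave the 15 lists and 0 genes. The split of Mdmx-Tg 1, Mdmx-Tg 2 and Mdmx-Tg/Pu.1-URE-/- 1 from the rest does so too and gave the 13. Splits that do not gave up to 12 lists in each of these comparisons, so a role of the series was not shown in them. With the series as a block, 1 and 9 lists passed for Mdmx-Tg against Wild-type and the double mutant against Mdmx-Tg.

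The number of genes called between Pu.1-URE-/- and Wild-type was weighed against plasma cell RNA and immunoglobulin reads. With Jchain as a covariate 409 of the 707 genes were called again, and with immunoglobulin genes left out 669, which argues against either as the whole cause in this comparison. For the double mutant, 103 of the 348 genes against Mdmx-Tg and 164 of the 502 against Wild-type were called again with Jchain. With Y-linked expression as a covariate 92 and 178 were called, so a loss of this size was not particular to Jchain. Immunoglobulin genes took on average 2.20% of reads in the double mutant, 7.10% in Mdmx-Tg and 14.0% in Wild-type, with overlapping ranges. More plasma cell RNA in the latter genotypes would give genes lower in the double mutant. Only 97 and 131 of the called genes were lower. This argues against plasma cell RNA for the genes called higher, but leaves it open for the lower ones. With immunoglobulin genes left out 338 and 480 were called again. The log2 change between Pu.1-URE-/- and Wild-type correlated with that in transgenic animals, from other libraries, at r = 0.595, above each of the other relabellings. Loss of the element would give this, but so would a change of cell content shared by the libraries without it. The correlation therefore does not separate these causes. Of the 10 splits of the 6 libraries, which are too few for a share under 0.05, the real one gave 707 genes and the highest other gave 1.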
